A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

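The data are 6 one-colour Affymetrix arrays of total RNA from Saccharomyces cerevisiae, 3 from the H4R45H strain and 3 from the wild-type strain WY139. Per the labels, cells were grown in YPD, a rich medium with glucose, harvested at an optical density of 0.5 to 0.7, frozen in liquid nitrogen and extracted with hot acid phenol, and about 20 µg of total RNA was turned into biotin-labelled cRNA. The values are intensities on a linear scale, deposited by the authors as 1 signal per probe set, and the submitters' processing notes name MAS5, Affymetrix's method that summarises the probe pairs of a set into a signal and usually scales each array to a common mean. Its version, scaling target and detection calls were not given in the sources used here. The mean signal per array was 277 to 287 and the highest signal 1919 to 2339. Whether the top of this range is compressed or saturated is not known, so differences of bright genes, such as those for histones, ribosomal proteins and glycolysis, may be understated.

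Groups were taken from the labels. Probe sets were named from the platform annotation, and symbols were updated through the Entrez identifier. Of 5716 probe sets 5498 had 1 gene, 0 had several and 218 had none there, and all 5449 genes were matched to the RefSeq gene table. No column of another sample was present or used. A gene was represented by its probe set with the highest mean log2 signal. Of 47 genes with several probe sets, 14 had probe sets with differing calls and 1 had calls in opposite directions. Of the probe sets 132 are of a type that can bind several transcripts, and 115 genes were read from such a set. At most 0.63% of values were identical between any 2 arrays, so no array was a copy of another. The median SD of log2 signal within a strain was 0.076 for wild type and 0.085 for H4R45H.

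Signals were taken as log2 with no further scaling, and 7 values at 0, in 3 probe sets, were set to 0.1, the smallest positive value. limma 3.58.1 in R 4.3.3 fitted the strain difference per probe set (lmFit and eBayes with trend), two-sided, with Benjamini-Hochberg adjustment over all 5716 probe sets, and a gene was called at an adjusted p under 0.05. Rose, fell, higher and lower are used of called genes, and all differences are H4R45H against wild type. Errors of means are SD over the 3 arrays, and SE is that of the log2 difference. Folds are from the fitted log2 difference, so for dim genes they depend on the floor of the signal. No coordinates are given because no genome was used.

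The names of 43 gene lists were fixed before the data were examined, and 41 of them were tested. The alpha-specific list was below the minimum of 5 measured genes and the strain markers were given gene by gene. limma's camera compared each list with all other genes at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 41 lists, and camera with an estimated correlation and fry were run beside it. The subtelomeric list was made from systematic ORF names, the 10 outermost per arm. The brightness-matched comparisons drew 10000 random lists within 20 classes of mean signal, from all genes, the members of the list included.

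The genes named were set by a rule fixed before the data were examined. It takes the histone genes, the 12 largest rises and the 12 largest falls among called genes whose strains do not overlap and whose mean lies above the lowest 25% of probe sets (a signal of 78.3), up to 4 called members of each list by size of difference, and the strain markers. Alternatives fixed beforehand were quantile normalization, median centring, a pseudocount of 50, no variance trend, leaving out the dimmest 25% of probe sets, the replicate block, leaving out each array, a minimum of 2-fold, the mean of a gene's probe sets, the estimated correlation, and 5 or 20 outermost ORFs. Cyclic loess normalization and leaving out probe sets that can bind several transcripts were added after seeing the data.

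The fit was tested on simulated data for H4R45H against wild type with 3 arrays each and 5716 probe sets. Of 50 probe sets changed by 0.25 on the log2 scale 38% were recovered with the right sign, of 50 changed by 0.5 92%, and of 50 changed by 1 and 50 changed by 1.5 100% each. Of 5516 unchanged probe sets 15 were called, beside 19, 46, 50 and 50 changed ones recovered, in order of size. In the list test on 5449 genes, 0 lists were called with no list shifted, and 1 was called when only the proteasome list was raised by 0.5. The simulated genes vary independently, which real genes do not. Few simulated probe sets were changed, and none shifted with brightness, while 66.2% of the real genes were called. The simulation therefore does not test the fit in that setting.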

Results

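Messenger RNA was measured in the budding yeast Saccharomyces cerevisiae with one-colour Affymetrix oligonucleotide arrays. A strain whose histone H4 carries the substitution R45H (arginine to histidine at residue 45, numbered along the H4 protein) was set against the wild-type strain WY139, with 3 arrays per strain. R45H is known as a Sin mutation, a class that relieves the need for the SWI/SNF chromatin remodelling complex at some promoters. Both strains grew in rich medium with glucose to mid-log phase. The question of the comparison was which transcripts a single changed residue in the globular part of H4 affects. Each array gave a signal for 5716 probe sets, of which 5498 had a gene name, for 5449 genes in all. The median signal was 148 to 151 on the wild-type arrays and 159 to 163 on the H4R45H arrays. Correlations of log2 signal across probe sets, which are not independent replicates, were 0.993 to 0.994 between wild-type arrays, 0.9902 to 0.995 between H4R45H arrays and 0.935 to 0.958 between the strains. The number of arrays limits the precision. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

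The probe set for histone H4 did not pass the test. Histone H4 has the gene copies HHF1 and HHF2, and the probe set named for HHF1 (YBR009C) is of a type that can bind several transcripts, while no probe set was named for HHF2. Its signal was 1197 ± 30.8 (SD, n = 3) in wild type and 1173 ± 96.1 (SD, n = 3) in H4R45H, a log2 difference of -0.03 (SE 0.058, adjusted p = 0.64). A point mutation leaves the probe set's target in place, so this is a level and not a check of the labels. HHT1, the neighbour of HHF1, was listed near the bottom of the scale in both strains, so which H4 copy the probe set measured is not known. The difference turned to 0.12 after quantile normalization (adjusted p = 0.070) and to 0.14 after cyclic loess normalization, chosen after seeing the data (adjusted p = 0.047). Other core and variant histones were measured beside it. HTB2, which encodes H2B, fell from 1034 ± 58.0 to 626 ± 58.8 (SD, n = 3; log2 difference -0.73, SE 0.072, adjusted p = 1.0e-05), and HTZ1, which encodes the variant H2A.Z, fell by 0.58 on the log2 scale (SE 0.058, adjusted p = 1.2e-05). Smaller differences passed the test for HTB1 (log2 difference -0.30), linker histone HHO1 (-0.18) and HTA2 (-0.14, from a probe set that can bind several transcripts), and all 3 calls were lost after quantile normalization. There HTB1 had -0.15 (adjusted p = 0.096), HHO1 -0.17 (adjusted p = 0.064) and HTA2 0.05. HHO1 was also lost after cyclic loess, without the variance trend, with the replicate block and without the dimmest 25% of probe sets (adjusted p = 0.051 to 0.30). Leaving out wild type replicate 1 or 2 or H4R45H replicate 1 or 2 lost it too (adjusted p = 0.083 to 0.21). HTA2 was also lost without the variance trend or wild type replicate 3 (adjusted p = 0.057 and 0.059). HTA1 had a log2 difference of 0.00 (adjusted p = 0.93), which became 0.16 after quantile normalization with an adjusted p of 0.0022. HHT2 had a difference of 0.06 (adjusted p = 0.23) and the centromeric variant CSE4 one of -0.02 (adjusted p = 0.86). Both were called after quantile normalization, at 0.23 (adjusted p = 0.0016) and -0.27 (adjusted p = 0.0059). HHT1 was at 1.77 ± 1.42 and 3.0 ± 0.458 (SD, n = 3), against 1679 ± 55.7 for HHT2 in wild type, with a log2 difference of 1.05 (adjusted p = 0.11) that was called without wild type replicate 3 (1.67, adjusted p = 0.010) and was -0.05 after cyclic loess. The histone list, with 5 of 10 measured genes lower (4 when adjusted over the list alone) and 3 lower and 2 higher after quantile normalization, was not called as a list (adjusted p = 0.096).

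Stress, carbon-source and subtelomeric genes were among those that rose most in H4R45H, and genes for ribosome assembly, translation and iron uptake among those that fell most. In the limma fit 3605 of the 5449 genes differed, 2022 higher and 1583 lower, which is 66.2% of the genes. With a minimum of 1.5-fold, 979 genes were higher and 234 lower, and with a minimum of 2-fold 484 were higher and 21 lower. The 2-fold split was 261 and 90 after quantile normalization, 305 and 69 after cyclic loess, 417 and 39 after median centring, 126 and 6 with a pseudocount of 50, and 502 and 33 without H4R45H replicate 1. The 3 values of each strain did not overlap for 71.5% of genes, against 10% by chance. Dim probe sets were higher in H4R45H as a body. In the dimmest 10% of probe sets (median signal 18.3) the median log2 difference was 0.71, and in the brightest 10% (median signal 1104) it was -0.18. The split between higher and lower moved with the scaling. As deposited 56.1% of the called genes were higher, against 42.2% after quantile normalization (1464 higher, 2006 lower) and 50.3% after cyclic loess (1673 higher, 1654 lower). It was 44.0% after median centring (1651 higher, 2105 lower), which shifts all genes of an array alike, and 45.5% without the dimmest 25% of probe sets (1232 higher, 1478 lower). The median log2 difference of all genes was 0.05 as deposited and -0.07 after quantile normalization, so differences given below are 0.05 smaller when set against all genes. Under the deposited scale, quantile normalization, median centring and cyclic loess alike, 1249 genes were called higher and 1215 lower. At 1.5-fold or more, 534 genes were higher and 172 lower under all of these.

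**Figure D1:**
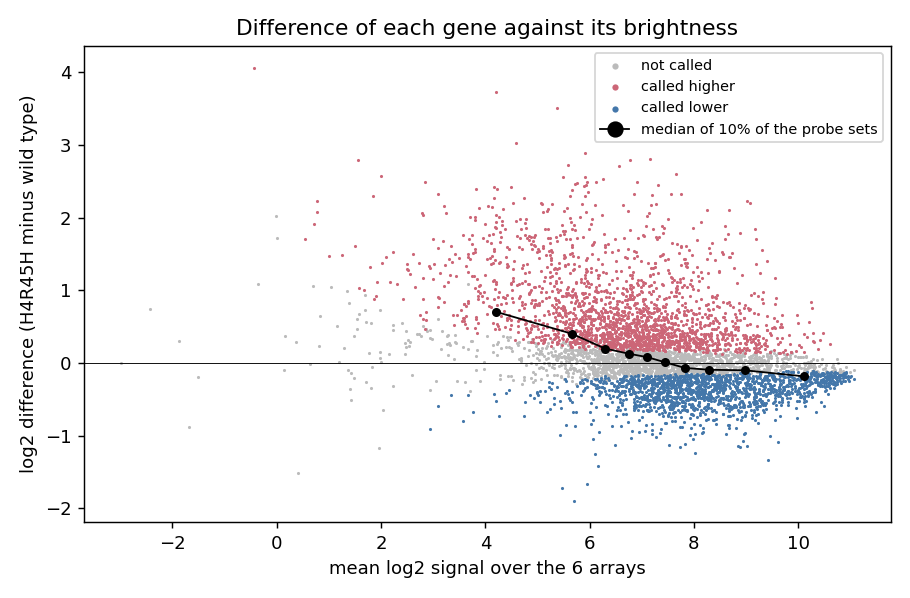
Log2 difference (H4R45H minus wild type) of each of 5449 genes against its mean log2 signal over the 6 arrays, coloured by whether the gene was called higher, lower or neither. The black line joins the medians of classes that each hold 10% of the probe sets, which run from 0.71 in the dimmest class to -0.18 in the brightest.

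The 12 largest rises among genes above the lowest 25% of signal were between 4.6-fold and 7.01-fold. PMA2 (YPL036W), a second plasma membrane proton pump, rose from 54.7 ± 9.14 to 381 ± 35.2 (SD, n = 3; 7.01-fold, adjusted p = 4.5e-08). RTN2, a reticulon of the endoplasmic reticulum, rose 6.90-fold, the hexose transporter HXT9 6.51-fold, RTC3 6.07-fold and EGO4 5.61-fold. SRX1, the sulfiredoxin that repairs oxidised peroxiredoxins, rose 5.44-fold, from 68.2 ± 11.2 to 370 ± 52.0 (SD, n = 3; adjusted p = 1.1e-07). HBT1 rose 5.02-fold, RGI1 5.0-fold, the biotin synthesis gene BIO4 4.99-fold and VPS73 4.95-fold. SER3, which encodes a phosphoglycerate dehydrogenase of serine synthesis, rose from 238 ± 12.6 to 1119 ± 50.7 (SD, n = 3; 4.70-fold, adjusted p = 9.2e-09). The small heat shock protein gene HSP26 rose from 253 ± 21.2 to 1163 ± 77.8 (SD, n = 3; 4.6-fold, adjusted p = 2.2e-08). The signal limit applies to the mean over all 6 arrays, so a gene that rises can pass through its H4R45H signal. Wild-type signals of PMA2, RTN2, HXT9, EGO4, SRX1, HBT1 and VPS73 lay below the limit of 78.3. With a pseudocount of 50 PMA2 was 4.12-fold and HXT9 3.35-fold higher.

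The 12 largest falls among genes above the same lowest 25% of signal were between 2.06-fold and 2.53-fold. RPS22B (YLR367W), a protein of the small ribosomal subunit, fell from 1089 ± 12.9 to 431 ± 13.3 (SD, n = 3; 2.53-fold, adjusted p = 2.2e-08). Iron uptake genes were among them. FIT2, a cell wall protein that retains siderophore-bound iron, fell 2.37-fold, the ferroxidase gene FET3 fell from 704 ± 11.3 to 315 ± 11.3 (SD, n = 3; 2.24-fold, adjusted p = 6.0e-08), and the ferric reductase gene FRE4 fell 2.18-fold. PUF6 and RRP1, which act in assembly of the large ribosomal subunit, fell 2.20-fold and 2.06-fold. PRS1, which makes the ribose phosphate precursor of nucleotides, fell 2.21-fold. YDR292C, a receptor subunit for the signal recognition particle, fell 2.17-fold, and UTR2, a cell wall transglycosylase, fell 2.12-fold. SSP120, YHR175W-A and HRI1 fell 2.24-fold, 2.19-fold and 2.10-fold. SPL2 (3.72-fold) and MMP1 (3.16-fold) fell more, but their means over the 6 arrays lay below the signal limit. The sizes of the rises and falls named by this rule therefore depend on the limit.

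**Figure D2:**
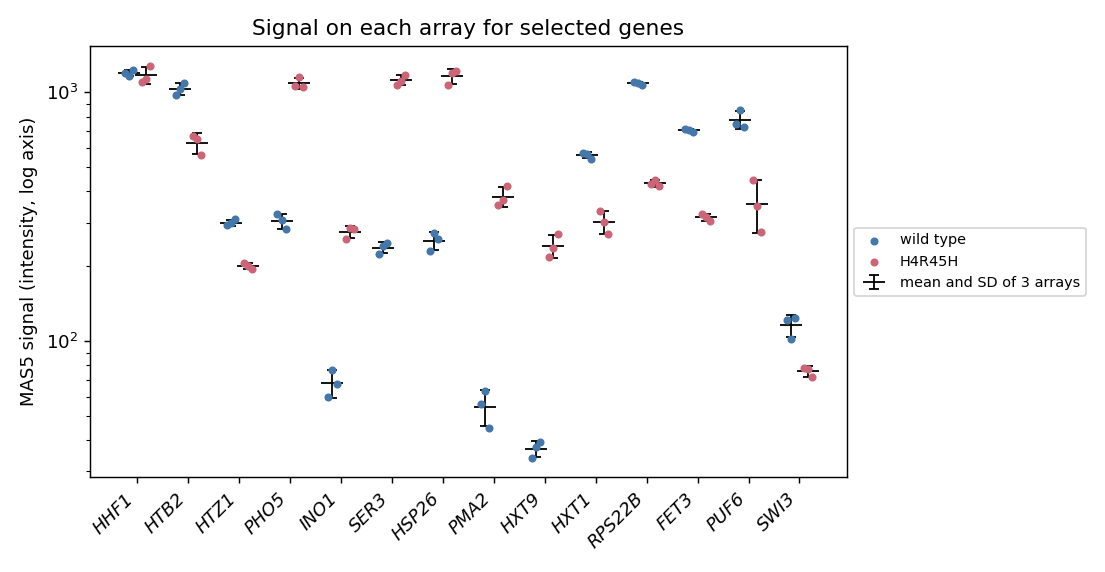
MAS5 signal (log axis) of 14 genes on each of the 3 wild-type and 3 H4R45H arrays, with the mean and SD of each strain in black. HHF1 overlaps between the strains, while PHO5, INO1, SER3, HSP26, PMA2 and HXT9 lie higher and HTB2, HTZ1, HXT1, RPS22B, FET3, PUF6 and SWI3 lower on all 3 H4R45H arrays.

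Gene lists fixed before the data were examined were tested with camera. Of 41 lists tested, 15 were called up and 6 down with the preset correlation of 0.01. With a correlation estimated from the 6 arrays 0 lists were called, and 2 had an unadjusted p under 0.05, the smallest adjusted p being 0.35. The rotation test fry, which does not compare a list with other genes, called 31 lists. The same camera test called 12 to 20 lists in each of the other 9 splits of the 6 arrays into groups of 3, each of which keeps part of the strain difference by its make-up. The p-values of the lists are therefore weak support, and the counts and sizes of their members are given beside them. The counts have a background that depends on brightness. Of the dimmest 10% of probe sets 63.3% were called higher, and of the brightest 10% 66.6% were called lower. Counts near such shares do not set a list apart. Of the 21 called lists, 5 had medians inside the central 95% of random lists of the same brightness. These ranges were 0.01 to 0.36 for other DNA repair, -0.02 to 0.65 for pheromone induced, -0.13 to 0.46 for PAU, -0.24 to -0.12 for glycolysis and -0.23 to -0.04 for amino acid biosynthesis. Counts adjusted over the list alone were the same as those over all genes unless given.

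General stress genes, those with the Msn2/4 type of control, rose together. Of 40 measured, 38 rose and the other 2 did not pass, with a median log2 difference of 1.35 (adjusted p = 1.6e-12 with the preset correlation; adjusted p = 0.38 with an estimated correlation). RTN2, the transketolase TKL2 (5.42-fold), HSP26 and the phosphogluconate dehydrogenase GND2 (4.56-fold) had the largest differences. Among 110 ribosome biogenesis genes 106 fell (107 when adjusted over the list alone) and the other 4 did not pass, with a median of -0.52 (adjusted p = 6.1e-20; adjusted p = 0.41 with an estimated correlation). PUF6 and RRP1 fell most, followed by the rRNA methyltransferase RRP8 (log2 difference -0.88) and the helicase ROK1 (-0.80). Of 122 cytosolic ribosomal protein genes, 116 fell, with a median of -0.23 (adjusted p = 6.1e-20; adjusted p = 0.35 with an estimated correlation). RPS22B, RPL41A (log2 difference -0.98, from a probe set that can bind several transcripts), RPS27A (-0.68) and RPS9A (-0.60) led them. Random lists of the same brightness had medians of -0.19 to -0.16 (central 95%), just above that of the ribosomal protein genes. These genes are many among the brightest (median signal 1535), and the random lists could draw them. That range is therefore not independent of the list. After quantile normalization the median was -0.06, with 46 lower and 1 higher.

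Genes of respiration and of carbon sources other than glucose were higher. In the glucose-repressed list 23 of 24 genes rose and 1 fell, with a median of 1.21 (adjusted p = 5.2e-08; adjusted p = 0.38 with an estimated correlation). The lactate transporter JEN1 rose from 26.1 ± 0.693 to 142 ± 3.58 (SD, n = 3; 5.44-fold), and the gluconeogenic enzyme FBP1 (5.35-fold), the fatty acid thiolase POT1 (5.19-fold) and the Ato family transporter ATO2 (4.55-fold) rose with it, all from dim signals. Among 18 genes of the TCA cycle 14 rose, with a median of 0.43 (adjusted p = 7.1e-04; adjusted p = 0.38 with an estimated correlation), led by CIT3 (3.58-fold), SDH1 (2.03-fold), SDH4 (1.79-fold) and CIT1 (1.59-fold). Of 31 respiratory chain genes 15 rose and 2 fell (1 when adjusted over the list alone), with a median of 0.15 (adjusted p = 0.046; adjusted p = 0.35 with an estimated correlation). After quantile normalization 21 were higher and 0 lower (adjusted p = 3.5e-06). NDI1 rose 1.84-fold, CYT1 1.33-fold, CYC1 1.32-fold and QCR10 1.31-fold. The respiratory call was lost after median centring (adjusted p = 0.21), without the variance trend (adjusted p = 0.068) and without any single wild-type array (adjusted p = 0.055 to 0.071). Galactose and maltose genes had 10 of 12 higher and 1 lower (median 0.97, adjusted p = 0.0021; adjusted p = 0.35 with an estimated correlation), with a median of 0.50 after quantile normalization (8 higher, 2 lower), among them GAL1 (2.88-fold), GAL3 (2.40-fold), MPH2 (2.57-fold) and MAL32 (2.15-fold). MPH2 and MAL32 were read from probe sets that can bind several transcripts. Hexose transporters had 12 of 17 higher (13 when adjusted over the list alone) and 2 lower (median 0.92, adjusted p = 0.012; adjusted p = 0.38 with an estimated correlation), led by HXT5 (7.37-fold), HXT9, HXT11 (3.52-fold) and HXT7 (2.84-fold, from a probe set that can bind several transcripts). The hexose transporter median was 0.40 after quantile normalization (8 higher, 3 lower), and the call was lost without the dimmest 25% of probe sets (median 0.60, adjusted p = 0.15) and after cyclic loess normalization (adjusted p = 0.058). For 16 genes of glycolysis and fermentation the median was -0.13, with 10 lower and 1 higher (adjusted p = 0.029; adjusted p = 0.67 with an estimated correlation). After quantile normalization that median turned to 0.05, with 2 higher and 1 lower and no call (adjusted p = 0.13), and the call was also lost without the dimmest 25% (adjusted p = 0.12). TDH1 rose 1.79-fold and PFK2 fell (log2 difference -0.27). After quantile normalization CIT3 was 2.14-fold, FBP1 3.27-fold, MPH2 1.55-fold and GAL3 1.56-fold higher. HXK2 (-0.23) and PFK1 (-0.20) were called lower as deposited and not after quantile normalization (-0.07, adjusted p = 0.096, and -0.04, adjusted p = 0.33).

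**Figure D3:**
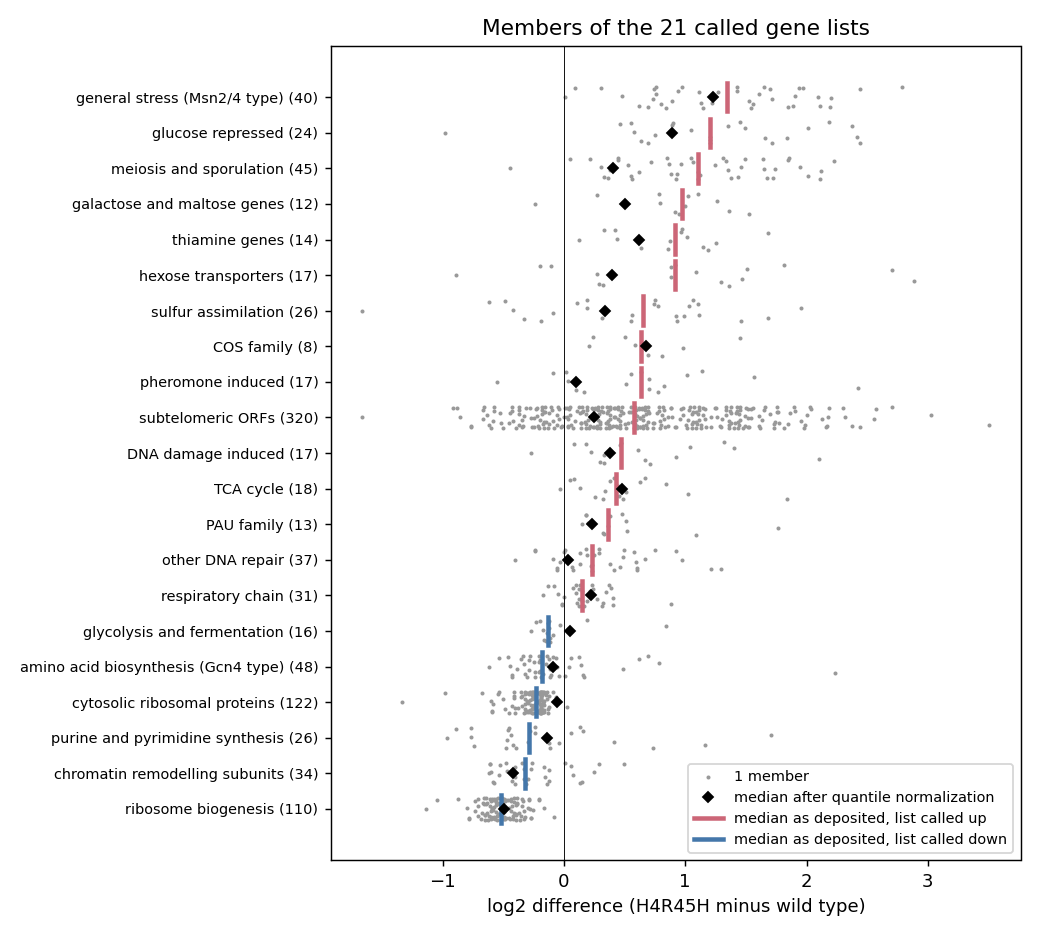
Log2 differences (H4R45H minus wild type) of the members of the 21 gene lists called by camera with the preset correlation, with the number of measured members in brackets. Grey points are genes, coloured bars the medians as deposited (1.35 for general stress, -0.52 for ribosome biogenesis) and black diamonds the medians after quantile normalization, which change sign for glycolysis and fermentation.

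Genes near chromosome ends rose more often than others. The subtelomeric list holds the 10 outermost named ORFs of each chromosome arm, 320 genes, and of these 211 rose and 47 fell (215 and 48 when adjusted over the list alone). The median was 0.58 (adjusted p = 4.5e-08; adjusted p = 0.35 with an estimated correlation) and 0.25 after quantile normalization, with 161 higher and 68 lower. It was 0.26 without the dimmest 25% of probe sets, 0.26 with a pseudocount of 50 and 0.24 over the 20 outermost ORFs. The sulfonate dioxygenase JLP1 rose from 12.5 ± 2.35 to 141 ± 11.5 (SD, n = 3; 11.4-fold, adjusted p = 2.7e-08), MCH2 rose 8.13-fold, HXT9 6.51-fold and YHR213W 5.96-fold, the last from a signal of 2.70 ± 2.19 (SD, n = 3). Along the arms, in classes chosen after seeing the data, 72.5% of the 160 ORFs in places 1 to 5 from the end were higher (median 0.67) and 59.4% of the 160 in places 6 to 10 (median 0.41). In places 11 to 20 it was 34.7% of 320, with a median of 0.00, and from place 41 inwards 35.5% of 4188, with a median of 0.04. COS genes, a repeated subtelomeric family, rose in 8 of 8 (median 0.64, adjusted p = 0.0068; adjusted p = 0.35 with an estimated correlation), led by COS12 (2.73-fold), COS8 (1.98-fold), COS7 (1.75-fold) and COS6 (1.62-fold). COS7 was read from a probe set that can bind several transcripts. After quantile normalization 6 COS genes were higher and 1 lower. In the PAU family 9 of 13 rose (10 when adjusted over the list alone; median 0.36, adjusted p = 0.029; adjusted p = 0.64 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.057; 3 higher, 0 lower) and without H4R45H replicate 3 (adjusted p = 0.071), and the leading members PAU21 (3.41-fold), PAU3 (2.13-fold), PAU2 (1.44-fold) and PAU8 (1.42-fold) came from probe sets that can bind several transcripts. PAU3, PAU2 and PAU8 lost their calls after quantile normalization (adjusted p = 0.052, 0.29 and 0.085). YHR213W lost its call after cyclic loess (adjusted p = 0.092) and was 2.55-fold higher without wild type replicate 1 and 9.98-fold without wild type replicate 2. After quantile normalization MCH2 was 5.17-fold, YHR213W 3.25-fold and PAU21 1.90-fold higher. Of 15 silencing factors 4 were higher and 4 lower (adjusted p = 0.49, not called), but 0 higher and 9 lower after quantile normalization (median -0.25, adjusted p = 0.061). RAP1 fell by 0.75 on the log2 scale, ORC1 by 0.59 and the deacetylase SIR2 by 0.48, while RIF2 rose by 0.49 from a signal of 10.6, was called lower after quantile normalization (-0.43, adjusted p = 0.021) and lost its call without H4R45H replicate 1 (adjusted p = 0.052).

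**Figure D4:**
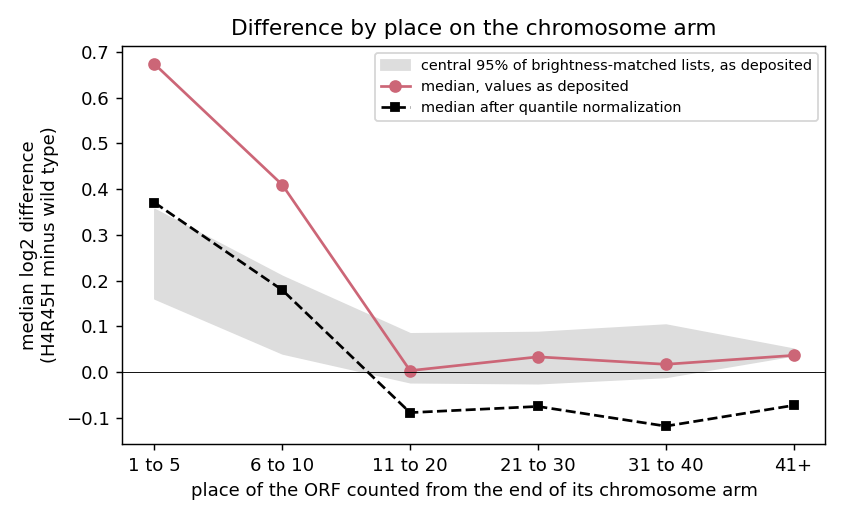
Median log2 difference (H4R45H minus wild type) of ORFs by their place counted from the end of the chromosome arm, as deposited and after quantile normalization. The grey band is the central 95% of 10000 random lists matched on brightness for the deposited values, and the first 2 classes (0.67 and 0.41) lie above it.

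Subunits of chromatin remodelling complexes were lower. Of 34 measured, 22 fell and 3 rose, with a median of -0.32 (adjusted p = 1.4e-04; adjusted p = 0.38 with an estimated correlation). SWI1 fell from 145 ± 11.9 to 94.2 ± 6.49 (SD, n = 3; log2 difference -0.62, SE 0.084), and SWI3, also of SWI/SNF, fell by 0.61. NPL6 and STH1, of the RSC complex, fell by 0.61 and 0.60. Genes known to depend on SWI/SNF moved in both directions. Of 9 measured, 7 rose and 2 fell, with a median of 0.89, and the list was not called as deposited (adjusted p = 0.056) but was after quantile normalization (median 0.56, adjusted p = 0.015), after median centring (adjusted p = 0.029) and without wild type replicate 1 or 2 or H4R45H replicate 2 (adjusted p = 0.035 to 0.050). INO1, for inositol synthesis, rose from 68.1 ± 8.66 to 275 ± 15.9 (SD, n = 3; 4.05-fold, adjusted p = 7.1e-08), the acid phosphatase PHO5 from 304 ± 21.2 to 1087 ± 57.4 (SD, n = 3; 3.58-fold, adjusted p = 2.2e-08) and GAL1 2.88-fold. HO, the mating-type switching endonuclease, fell from 160 ± 13.0 to 79.9 ± 21.9 (SD, n = 3; 2.05-fold, adjusted p = 4.3e-04). All 9 of these genes are also in other lists. The phosphate regulon was split, with 5 of 16 higher and 10 lower and a median of -0.43 (adjusted p = 0.057, not called; 0.046 without H4R45H replicate 3). PHO5, the phosphate transporter PHO89 (2.64-fold) and the glycerophosphoinositol transporter GIT1 (2.78-fold) rose, while SPL2 fell from 101 ± 13.0 to 27.1 ± 0.557 (SD, n = 3; 3.72-fold, adjusted p = 1.8e-07).

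DNA damage induced genes were higher, while the higher counts of other repair lists depended on the scaling. In the damage-induced list 15 of 17 rose and 1 fell, with a median of 0.47 (adjusted p = 7.4e-04; adjusted p = 0.35 with an estimated correlation). HUG1, a checkpoint target that restrains ribonucleotide reductase, rose from 149 ± 25.5 to 636 ± 93.5 (SD, n = 3; 4.28-fold, adjusted p = 3.5e-07), polyubiquitin UBI4 2.64-fold and the reductase subunit RNR3 2.5-fold. Of these 17 genes, 6 are in other lists too. Among 25 nucleotide excision repair genes 11 rose and 6 fell, with no call for the list (adjusted p = 0.62) and a median of 0.13 that became -0.03 after quantile normalization, with 4 higher and 6 lower. RAD2 rose 2.05-fold, from 70.4 ± 11.1 to 143 ± 9.71 (SD, n = 3; adjusted p = 1.4e-05), and RAD4 1.61-fold. RAD10 was 1.70-fold higher as deposited, with a log2 difference of 0.02 after quantile normalization (adjusted p = 0.91). RAD34 was 1.52-fold higher from a signal of 11.7, turned to a log2 difference of -0.33 after quantile normalization, and lost its call without H4R45H replicate 2 (adjusted p = 0.062). Other repair genes had 22 of 37 higher and 3 lower (median 0.23, adjusted p = 0.029; adjusted p = 0.38 with an estimated correlation), a call lost without the dimmest 25% of probe sets (median 0.13, adjusted p = 0.12) and after quantile normalization (adjusted p = 0.49), where 9 were higher and 9 lower with a median of 0.03. MUS81 rose 2.46-fold, XRS2 2.31-fold and MAG1 1.90-fold. APN2 was 1.96-fold higher as deposited and lost its call after quantile normalization (log2 difference 0.26, adjusted p = 0.11).

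Markers of cell type were measured as lists. The a-specific genes MFA1 (1.71-fold, from 330 ± 12.4 to 566 ± 43.5; SD, n = 3), AGA2 (1.39-fold) and BAR1 (1.38-fold) rose, as did ASG7 (1.42-fold) from a signal of 20.6 with a reversed sign after quantile normalization. In all 4 of 7 a-specific genes rose and 2 fell (adjusted p = 0.68, not called), and the median of 0.47 was 0.01 after quantile normalization. All 4 alpha-specific genes were called higher, and 2 after quantile normalization, too few for a list test, with dim signals for all but SAG1. STE3 went from 18.9 ± 2.46 to 55.5 ± 0.603 and SAG1 from 94.8 ± 1.93 to 247 ± 25.5 (SD, n = 3; 2.96-fold and 2.60-fold). The alpha factor genes MF(ALPHA)1 (1.5-fold) and MF(ALPHA)2 (1.84-fold) rose from signals of 9.63 and 13.3, both had differences below 0 after quantile normalization, and MF(ALPHA)1 lost its call without H4R45H replicate 1 (adjusted p = 0.080). Haploid-specific genes were 4 higher and 3 lower of 11 (adjusted p = 0.63, not called), and 1 higher and 4 lower after quantile normalization. Besides HO, GPA1 fell 1.47-fold. FUS1 (1.71-fold) and STE18 (1.34-fold) were called higher as deposited and not after quantile normalization (adjusted p = 0.13 for both). Of 17 pheromone-induced genes 11 rose and 1 fell (median 0.63, adjusted p = 0.029; adjusted p = 0.35 with an estimated correlation), led by PRM2 (5.38-fold), FIG1 (2.96-fold), PRM3 (2.20-fold) and AGA1 (2.02-fold). This call was lost without the dimmest 25% of probe sets (adjusted p = 0.41; median 0.04) and after quantile normalization (adjusted p = 0.26; median 0.10, 5 higher, 2 lower). Meiosis and sporulation genes rose in 40 of 45 and fell in 1, with a median of 1.11 (adjusted p = 9.8e-09; adjusted p = 0.38 with an estimated correlation) that was 0.41 after quantile normalization, with 25 higher and 5 lower. They were dim, with a median signal of 24.3, and random lists of the same brightness had medians of 0.34 to 0.88. The meiotic transcription factor NDT80 rose from 17.6 ± 0.681 to 76.7 ± 2.72 (SD, n = 3; 4.35-fold), MEI5 rose 4.69-fold from a signal of 0.867 with no call after cyclic loess (adjusted p = 0.065), SPO74 4.33-fold and the glucoamylase SGA1 4.04-fold. After quantile normalization STE3 was 1.88-fold, PRM2 3.18-fold, FIG1 1.69-fold, MEI5 2.43-fold and SPO74 2.51-fold higher.

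Vitamin and nutrient pathways moved in different directions. Thiamine genes rose in 14 of 14, with a median of 0.92 (adjusted p = 3.1e-05; adjusted p = 0.35 with an estimated correlation), led by THI73 (3.20-fold), SNZ3 (2.38-fold), THI2 (2.27-fold) and THI13 (2.21-fold). SNZ3 and THI13 were read from probe sets that can bind several transcripts. Sulfur assimilation genes had 17 of 26 higher (18 when adjusted over the list alone) and 6 lower, with a median of 0.65 (adjusted p = 0.029; adjusted p = 0.38 with an estimated correlation) that was 0.34 after quantile normalization. The call was lost without the dimmest 25% of probe sets (median 0.31, adjusted p = 0.055). The sulfate transporter SUL1 rose 3.89-fold, MET2 3.21-fold and MET28 2.75-fold, each from a dim signal, and the S-methylmethionine permease MMP1 fell from 110 ± 7.91 to 35.0 ± 3.46 (SD, n = 3; 3.16-fold). After quantile normalization SUL1 was 2.27-fold, MET2 1.99-fold, MET28 1.54-fold and THI2 1.49-fold higher. Amino acid biosynthesis genes had 27 of 48 lower and 7 higher, with a median of -0.18 (adjusted p = 0.0020; adjusted p = 0.38 with an estimated correlation), and the call was lost after quantile normalization (adjusted p = 0.49; median -0.09). The 4 largest differences in this list were rises, of SER3, ARG4 (1.72-fold), LYS1 (1.62-fold) and ORT1 (1.54-fold). Purine and pyrimidine genes had 17 of 26 lower and 4 higher, with a median of -0.29 (adjusted p = 0.0015; adjusted p = 0.35 with an estimated correlation), a call also lost after quantile normalization (adjusted p = 0.14; median -0.14). URA4 (1.95-fold) and ADE13 (1.85-fold) fell, while URA10 (3.26-fold) and IMD2 (2.24-fold, from a probe set that can bind several transcripts) rose. In the iron regulon 13 of 28 fell and 6 rose (adjusted p = 0.11, not called), with a median of -0.04 that was -0.26 after quantile normalization. FIT2, FET3 and FRE4 fell, as given above, and the siderophore transporter ARN2 rose 2.59-fold. The zinc regulon had 6 of 10 higher and 3 lower (adjusted p = 0.44, not called), with a median of 0.31 that was 0.04 after quantile normalization and ADH4 (1.55-fold) and the transporter ZRT1 (1.54-fold) higher and ADE17 (1.35-fold) lower.

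Protein folding, redox and cell wall genes included large single rises without a list call on the deposited scale. Of 22 heat shock genes 13 rose and 2 fell (adjusted p = 0.060), and the list was called up after quantile normalization (adjusted p = 2.0e-05), without the dimmest 25% of probe sets (adjusted p = 0.027) and without wild type replicate 2 or H4R45H replicate 1 (adjusted p = 0.035 and 0.0090). SSA3 rose 2.46-fold, the chaperone HSP82 from 401 ± 52.0 to 950 ± 128 (SD, n = 3; 2.37-fold), HSP42 2.21-fold and CUR1 2.15-fold. Oxidative stress genes had 13 of 28 higher and 7 lower (adjusted p = 0.45; 0.0036 after quantile normalization), with SRX1, the peroxiredoxin TSA2 (4.25-fold), AAD6 (3.63-fold) and AAD14 (2.83-fold) leading. Cell wall genes had 14 of 32 higher and 10 lower (adjusted p = 0.63; 9.7e-04 after quantile normalization, with 19 higher and 4 lower). The flocculin FLO1 rose 4.52-fold, PIR3 3.71-fold, the glucan synthase GSC2 3.26-fold and FLO9 2.70-fold, the last from a probe set that can bind several transcripts. Proteasome genes had 7 of 32 higher and 1 lower (5 higher and 0 lower when adjusted over the list alone; adjusted p = 0.39; 4.7e-04 after quantile normalization, with 15 higher and 0 lower), with the regulator RPN4 at 1.5-fold, PRE7 at 1.29-fold, RPN12 at 1.21-fold and RPN5 at 1.18-fold. RPN5 lost its call after median centring (adjusted p = 0.061). Hypoxic genes had 13 of 20 higher and 3 lower (adjusted p = 0.056; 0.019 after quantile normalization and 0.024 to 0.045 after median centring, without the dimmest 25%, or without wild type replicate 2 or H4R45H replicate 1 or 2), among them CYC7 (2.69-fold), ANB1 (2.38-fold), AUS1 (2.21-fold) and COX5B (1.99-fold).

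Cell cycle, lipid and mitochondrial ribosome lists were not called on the deposited scale. G1/S genes had 7 of 33 higher and 11 lower (9 lower when adjusted over the list alone; adjusted p = 0.13), and 7 higher and 20 lower after quantile normalization. POL2 (1.44-fold), the cyclin CLN1 (1.43-fold) and POL1 (1.34-fold) were lower, and ASF2 was 1.58-fold higher as deposited with no call after quantile normalization (adjusted p = 0.35). G2/M genes had 5 of 18 higher (4 when adjusted over the list alone) and 3 lower (adjusted p = 0.70), and 2 higher and 7 lower after quantile normalization. CLB1 was lower (1.33-fold) and DBF2 higher (1.30-fold), while YHP1 (1.30-fold) and HST3 (1.26-fold) were higher as deposited with no call after quantile normalization (adjusted p = 0.068 and 0.056). M/G1 genes had 5 of 21 higher and 9 lower (adjusted p = 0.096; 0.042 without H4R45H replicate 2), with DSE3 (1.81-fold), DSE4 (1.58-fold) and AMN1 (1.36-fold) lower and PST1 (1.76-fold) higher. Ergosterol genes had 3 of 26 higher and 9 lower (median -0.02, adjusted p = 0.18), and 12 higher and 3 lower after quantile normalization (median 0.08, adjusted p = 0.072). ERG4 (1.31-fold), ERG29 (1.21-fold) and NCP1 (1.18-fold) were lower and MVD1 (1.31-fold) higher, and NCP1 lost its call after cyclic loess (adjusted p = 0.071). Inositol and phospholipid genes had 6 of 19 higher and 7 lower (adjusted p = 0.57), with INO1, OPI3 (1.95-fold) and CHO1 (1.43-fold) higher and HNM1 (1.41-fold) lower. The median and the test of that list pointed down while its mean was 0.11, and for the G2/M list the mean was 0.02 while the median was -0.01. Mitochondrial ribosomal protein genes had 21 of 66 higher and 8 lower (17 and 6 when adjusted over the list alone; adjusted p = 0.60), and 13 higher and 12 lower after quantile normalization. RSM19 rose 1.46-fold, MRPL17 and MRPL8 fell 1.55-fold and 1.5-fold, and MRP8, which the list holds by its name, rose 1.68-fold.

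Genes often used as strain markers also differed. LEU2 was higher in H4R45H, at 394 ± 30.4 against 250 ± 25.3 (SD, n = 3; 1.58-fold, adjusted p = 6.3e-05), as were MET17 (1.48-fold) and ADE2 (1.33-fold). URA3 was lower, at 26.0 ± 2.54 against 36.2 ± 1.87 (SD, n = 3; 1.39-fold, adjusted p = 0.0027), and by 2.31-fold after quantile normalization. HIS3 had a log2 difference of 0.15 that passed narrowly (adjusted p = 0.044). Its call was lost without wild type replicate 1 or 3 or H4R45H replicate 2 or 3 (adjusted p = 0.065 to 0.16). It was also lost without the variance trend (adjusted p = 0.082), with the replicate block (adjusted p = 0.076) and after median centring (adjusted p = 0.52). CAN1 had a difference of -0.13 (adjusted p = 0.089), called after median centring (-0.23, adjusted p = 0.0085) and without wild type replicate 3 (adjusted p = 0.023), and LYS2 one of 0.01 (adjusted p = 0.91).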

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

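Probe sets with no gene name lie outside the comparisons of named genes. Of 218 such probe sets 119 were called higher in H4R45H and 34 lower, and at 1.5-fold or more 71 were higher and 5 lower. Their median log2 difference was 0.27 and their median signal 102. After quantile normalization 86 were higher and 56 lower, and these probe sets were not tested as a list or set against others of the same brightness. Groups of 3 arrays are too small for a test of single outlying arrays.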

How the results depend on the processing

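Cyclic loess normalization and leaving out shared probe sets were chosen after seeing the data. The 3605 called genes became 2710 to 3756 under other scalings, pseudocount, trend, dim filter and probe set choices, and 3249 to 3486 without single arrays. A minimum of 2-fold as well as the threshold gave 505 by its construction. Without the dimmest 25% 1232 genes were higher, from fewer genes tested. Genes at least 1.5-fold higher numbered 589 after quantile normalization, 426 with a pseudocount of 50 and 437 without the dimmest 25%. Those at least 1.5-fold lower numbered 468 after quantile normalization, 419 after median centring and 104 with the pseudocount, which shrinks dim differences by construction. The number of called lists was 16 to 24 in every setting but the estimated correlation, which gave 0. HHF1 had an adjusted p of 0.047 after cyclic loess, against 0.070 to 0.93 elsewhere, and its log2 difference was 0.0093 without H4R45H replicate 1. Differences that turned sign after quantile normalization and cyclic loess were -0.28 and -0.12 for ASG7, 0.12 and 0.14 for HHF1, 0.16 and 0.19 for HTA1, 0.047 and 0.044 for HTA2, -0.33 and -0.18 for MF(ALPHA)1, -0.33 and -0.12 for RAD34, -0.43 and -0.27 for RIF2, and 0.050 and 0.067 for the glycolysis median. MF(ALPHA)2 turned to -0.041 after quantile normalization only. Beyond the arithmetic named here, the cause was not tested. Of 180 named genes called, 160 kept their call and direction after quantile normalization, 163 after cyclic loess, and 174 without each array in turn. Of 21 called lists 15 kept theirs after quantile normalization, 14 after cyclic loess and 18 without each array, the others being PAU, glycolysis (adjusted p = 0.060 without wild type replicate 2 and 0.091 without H4R45H replicate 1) and respiratory chain. Without the dimmest 25% 14 of 19 kept theirs, 5 were lost and 2 lists gained one, and the meiosis and galactose and maltose lists had too few genes left. The pseudocount kept all 21, with medians of 0.20 for hexose transporters, 0.24 for pheromone induced and 0.32 for meiosis. A sign differed with no call on either side 7 times among lists. Same-numbered arrays deviated together with correlations of 0.027, -0.017 and -0.034, and 0 of 6 arrays correlated best with their own number. No pairing by number was seen, but with 3 arrays per strain this cannot exclude a culture or day shared by same-numbered arrays. With the replicate block 3480 genes and 21 lists were called, and 178 of the 180 named genes kept their call. Signals near the floor limit what dim genes can show.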

Other observations

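The tests of gene families by name and of dim probe sets were chosen after the result was seen, and the other tests here before it. Gene families were defined by a name prefix shared by at least 8 genes, leaving out genes of the fixed lists other than the subtelomeric one. Subtelomeric genes stayed in. Cytosolic tRNA synthetases and ORFs with only a systematic name were added without leaving out listed genes. Of 53 families tested with camera, 18 were called. Of these 12 kept their call and direction after quantile normalization and 13 after cyclic loess, and with an estimated correlation camera called 0, with 2 at an unadjusted p under 0.05. The families were not set against random lists of the same brightness. The set of tRNA synthetases, which charge tRNAs for translation, was written by hand and does not hold every such enzyme. All 19 in the set fell. Their median log2 difference was -0.41 (adjusted p = 2.5e-07, and adjusted p = 0.52 with an estimated correlation) and -0.26 after quantile normalization. FRS2 fell from 818 ± 20.9 to 511 ± 4.16 (SD, n = 3; 1.60-fold) and WRS1 1.53-fold. Of 15 TRM genes, mostly for tRNA modification, 13 fell (median -0.46, adjusted p = 3.6e-04; adjusted p = 0.60 with an estimated correlation), among them TRM112 (1.62-fold) and TRM3 (1.56-fold). Nucleoporin genes named NUP fell in 13 of 20 (median -0.28, adjusted p = 3.6e-04; adjusted p = 0.59 with an estimated correlation), NUP53 by 1.57-fold and NUP84 by 1.53-fold. Secretory pathway genes named SEC had 22 of 36 lower and 1 higher (median -0.20, adjusted p = 6.7e-04; adjusted p = 0.52 with an estimated correlation). In the other direction, autophagy genes named ATG had 28 of 34 higher and 1 lower (median 0.64 as deposited and 0.25 after quantile normalization, adjusted p = 1.7e-05; adjusted p = 0.52 with an estimated correlation), ATG34 from 41.2 ± 0.436 to 102 ± 7.32 (SD, n = 3; 2.48-fold) and ATG3 2.31-fold. Ubiquinone genes named COQ had 9 of 10 higher (median 0.34, adjusted p = 0.020; adjusted p = 0.52 with an estimated correlation), led by COQ11 (1.90-fold) and COQ4 (1.90-fold). Each of these families had the same direction and a call after quantile normalization and after cyclic loess.

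Dim probe sets were higher in H4R45H, by a median of 0.71 on the log2 scale in the dimmest 10%. An additive offset between the strains' arrays would add a similar linear signal to all dim probe sets. In the 4 dimmest classes of 10% the median linear differences were 6.85, 14.3, 10.4 and 9.48, a ratio of 2.09 between the largest and smallest. This lies between the values set for and against an offset, so an offset and a change in the dim transcripts cannot be told apart. The range of signal was narrower at both ends on all H4R45H arrays. The 5th percentile was 11.8 to 13.3 on the wild-type arrays and 23.9 to 24.9 on the H4R45H arrays. The 95th percentile was 1157 to 1187 and 1025 to 1071. This narrowing follows the strain, so a technical difference between the strains' arrays cannot be told apart from a change in the transcripts. Of 979 genes called at least 1.5-fold higher 575, or 58.7%, stayed so after quantile normalization, which brought the medians of all classes of 10% to between -0.09 and -0.02. About 5%, the false discovery rate, was set as the share that would stay with the trend as their whole source. This bound was set after the share was known, in place of earlier ones that left it undecided. The false discovery rate is not the share of such genes that the trend would leave, so the bound gives no verdict. The 575 genes kept at least 1.5-fold with the class medians flattened, and the trend stays open for the other 404 genes.

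Subtelomeric ORFs were higher in H4R45H, by a median of 0.58. Random lists matched on brightness had medians of 0.12 to 0.26 (central 95%), and the observed median was above all of them (percentile 100), which argues against low brightness. Without shared probe sets and the ORFs of 12 name prefixes held by several of them, the remaining 234 ORFs had a median of 0.43. The matched range was 0.10 to 0.26. Without genes of any other fixed list the remaining 229 had 0.53, above 0.14 to 0.30. The prefixes stood in for repeated families. COS, PAU, FLO and HXT were among them, but so were ARR, DAL, IRC and PHO, and a shared prefix does not show shared sequence. These medians argue against probe sets of the shared type with the ORFs of these 12 prefixes, and against the listed genes, as the whole source. Repeated genes whose prefix few ORFs held, and ORFs with only a systematic name, were not grouped. Genes outside the other lists stayed in. Shared signal among such ORFs, and stress or sugar genes outside the lists, were therefore not tested. The H4 substitution itself, the biological difference in the design, stays open and was not tested apart from other differences between the strains.

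Stress genes were higher and ribosome biogenesis genes lower, a combination known from slowing growth. The tables argue against brightness as the source, since the ribosome biogenesis median of -0.52 and the stress median of 1.35 lay outside the matched ranges of -0.18 to -0.03 and -0.18 to 0.10. A candidate explanation is that the H4R45H cultures were nearer to glucose exhaustion at harvest, for which high-glucose transporters should fall and low-glucose ones rise. HXT1 fell from 559 ± 16.1 to 302 ± 32.3 (SD, n = 3) and HXT3 from 1411 ± 56.4 to 1228 ± 15.4 (SD, n = 3), with a mean log2 difference of -0.55, while HXT2 (0.29), HXT4 (0.92) and HXT7 (1.51) rose, as that explanation needs, although the HXT3 call was lost after quantile normalization (adjusted p = 0.26). The labels give the same harvest range of optical density, 0.5 to 0.7, for both strains, so they name no difference in harvest. Altered glucose repression in the mutant could move these transporters the same way, so they do not single out the harvest. Slower growth or altered glucose repression in the mutant stays open and was not tested.

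The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. For the 3605 called genes, and for the 1213 called with at least 1.5-fold, 1 of the 10 splits, the real one, gave as many, and the highest of the others gave 0 in the limma fit, with 2 to 53 genes at an unadjusted p under 0.05. Each other split mixes the strains, which puts the strain difference into the spread within its groups. Their low gene counts therefore follow from their make-up and do not measure chance. For the called lists 1 of the 10 splits gave 21, and the highest of the others gave 20.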
